A study of Mus musculus with 8 samples.

How the data were processed

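Transcript abundance was measured by 3' end mRNA sequencing in naive mouse CD8+ T cells, purified with a magnetic kit for untouched naive CD8+ cells and then cultured for 24 h with 2 µM RGX-104 or with DMSO, per the labels' protocols. Each group held 4 libraries, and the group of each library came from its treatment label. Libraries are named here by group and library number, DMSO replicates 1 to 4 and RGX-104 replicates 5 to 8. Nothing in the labels says whether libraries of a group came from separate animals or separate cultures, so p-values measure the spread between these libraries, which may be technical. Library numbers are unique across groups and no batch or day is given, so no pairing or batch term was fitted. Unique numbers do not exclude that cells of the same animal were split between the groups.

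The deposited values are raw whole-number read counts per gene symbol, with 1 column per library and no normalization, per the file headers and the values themselves. The libraries were made with a QuantSeq kit, which primes on poly(A) and gives reads near the 3' end of transcripts, per the labels' protocols. STAR 2.7.8a, R 4.1.0, DESeq2 1.4 and the genome build GRCm38 are named in the submitters' processing notes, without a role for each. The counting tool, the annotation, the strand setting and any use of molecular identifiers are not given in the sources used here. Because the strand setting is unknown, reads of overlapping genes cannot be told apart, and reads shared by near-identical genes may have been split or dropped. A 3' end count reports on transcript number without a length correction, and it cannot show which isoform was made.

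The table held 41730 gene rows, of which 14589 had at least 1 count in any library. Of the symbols, 39351 (94.3%) were matched to the NCBI gene table of GRCm38.p6, from which gene coordinates were taken, 1-based. None of the 13 mitochondrially encoded protein genes fixed as a quality list was matched to a row, and neither were the constant regions of immunoglobulin and T cell receptor genes in the marker lists. These were not analysed here.

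Counts were tested with edgeR 4.0.16 (R 4.3.3), using the quasi-likelihood test with TMM normalization and the group as the only term. Genes were kept by filterByExpr with a minimum count of 10, which left 10037 genes. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Fold changes are RGX-104 over DMSO on the log2 scale with a standard error. This error is an approximation, the size of the log2 fold change divided by the square root of the quasi-likelihood F statistic. The 95% interval given for mt-Rnr1 rests on it. Levels are CPM, the counts of a gene scaled to a common library total, given as mean ± SD over 4 libraries.

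Gene lists, 27 in number, were fixed before the data were examined. They cover LXR targets, lipid synthesis and oxidation, naive, effector, activation, exhaustion, cell cycle, interferon, receptor, metabolic, stress and survival genes, RNA quality, CD8 T cell identity and markers of other cell types. A list with at least 3 tested members was compared with all other tested genes by camera (limma 3.58.1) on voom values with a preset inter-gene correlation of 0.01, two-sided, with adjustment over the 23 lists that could be tested. The same test was run with a correlation estimated from the data, and fry was run as a test of whether the members of a list move on balance in 1 direction. Counts of members past the threshold are given over all genes tested and adjusted over the list alone. The summed CPM of marker, identity and ribosomal protein lists was compared by a two-sided exact permutation test, whose smallest possible p for 4 against 4 libraries is 0.0286.

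Genes named in the text were chosen by a rule fixed before the data were examined. It takes the receptors Nr1h2 and Nr1h3, the LXR targets Abca1, Abcg1, Srebf1 and Mylip, and the T cell genes Cd8a, Cd8b1, Cd44, Il2ra, Gzmb, Ifng, Tbx21 and Eomes whether or not they pass. It adds up to 12 called genes per direction with the largest fold changes, a mean of at least 5 CPM and no overlap between the groups, and up to 4 called members of each list. Members of a list that did not pass may be given as values. Genes outside the rule are said to have been chosen after their values were seen. Some genes that the rule names, 1 of them among the called genes, are not reported here, although counts of genes and list tests include them.

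Total counts lay between 16196217 and 28287445 per library. The share of zeros among genes of low mean expression was much higher than such totals give for independent reads, so a number of apparent molecules was estimated for each library, chosen after the data were seen. It is the number that gives the observed zeros, under Poisson sampling, among genes with a mean of 2 to 20 CPM in the other 7 libraries. It came to 182352 to 344257 per library, or 48.9 to 115 reads for each apparent molecule, so that 1 molecule corresponds to 2.90 to 5.48 CPM. It also absorbs true differences between cells, and it is used to describe precision and in 1 added alternative. Floors given as 3 counts over a group cover counting error of reads only.

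The test was run on simulated data, in 5 simulations of the 10037 genes with 200 changed genes each. Among genes at 50 CPM or more it recovered 29.6% of 2-fold and 91.5% of 4-fold changes. Below 50 CPM it recovered 2.37% of 2-fold and 27.1% of 4-fold changes. Of 387 calls, 21 (5.43%) were false. Camera called the LXR list in 5 of 5 simulations and made 5 calls in 99 tests of lists that share no member with it. Those lists may hold some of the 200 changed genes. Simulated genes varied independently and the libraries differed only in total counts. The camera counts therefore do not show how often it calls a list wrongly in the real libraries.

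Alternatives fixed before the data were examined were 3 other normalizations (DESeq2 size factors, upper quartile, library size alone), no filter, a filter of at least 10 counts in 4 libraries, DESeq2 1.42.0, limma-voom, a robust dispersion, a test against a fold of 1.2, removal of mitochondrial and ribosomal protein genes, 1 surrogate variable (sva 3.50.0) and the removal of each library in turn. The mitochondrial genes removed were ribosomal and transfer RNA genes, because no mitochondrially encoded protein gene was matched to a row. Added after seeing the data were DMSO replicate 4 alone against RGX-104, the number of genes detected as a covariate, and counts divided by the apparent reads per molecule. With a group of 1 library the spread comes from the 4 RGX-104 libraries alone, the single DMSO library being assumed to vary like them. No library pair was a duplicate: counts of each pair differed with a chi-square of 68.6 to 194 per gene.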

Results

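Messenger RNA was counted in naive mouse CD8+ T cells after 24 h with 2 µM RGX-104, a synthetic agonist of the liver X receptors (LXR), or with its solvent DMSO. LXR are nuclear receptors that bind oxidised derivatives of cholesterol and drive genes of cholesterol export and fatty acid synthesis. The design holds a single comparison, 4 RGX-104 libraries against 4 DMSO libraries, and asks which transcripts the agonist changes in these cells. The title of the series speaks of a pre-effector state, so genes of naive, activated and effector T cells were examined beside the targets of the receptor.

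The DMSO libraries held 19448840, 18589856, 24353797 and 16308726 counts in all (replicates 1 to 4), and the RGX-104 libraries 28287445, 21332163, 16196217 and 16838693 (replicates 5 to 8). At least 1 count was found for 10047, 9772, 10194 and 10908 genes in the DMSO libraries and for 10442, 10748, 10803 and 10990 genes in the RGX-104 libraries. This number did not follow depth, and DMSO replicates 1, 2 and 3 had the lowest values, as the plot of depth and genes detected shows. The difference between the groups did not pass an exact two-sided permutation test (p = 0.114, n = 4 and 4). Genes with a mean of 5 to 10 CPM had no count in 18.7% to 23.3% of cases in DMSO replicates 1 to 3, in 8.30% in DMSO replicate 4 and in 7.07% to 13.3% in the RGX-104 libraries.

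**Figure D1:**
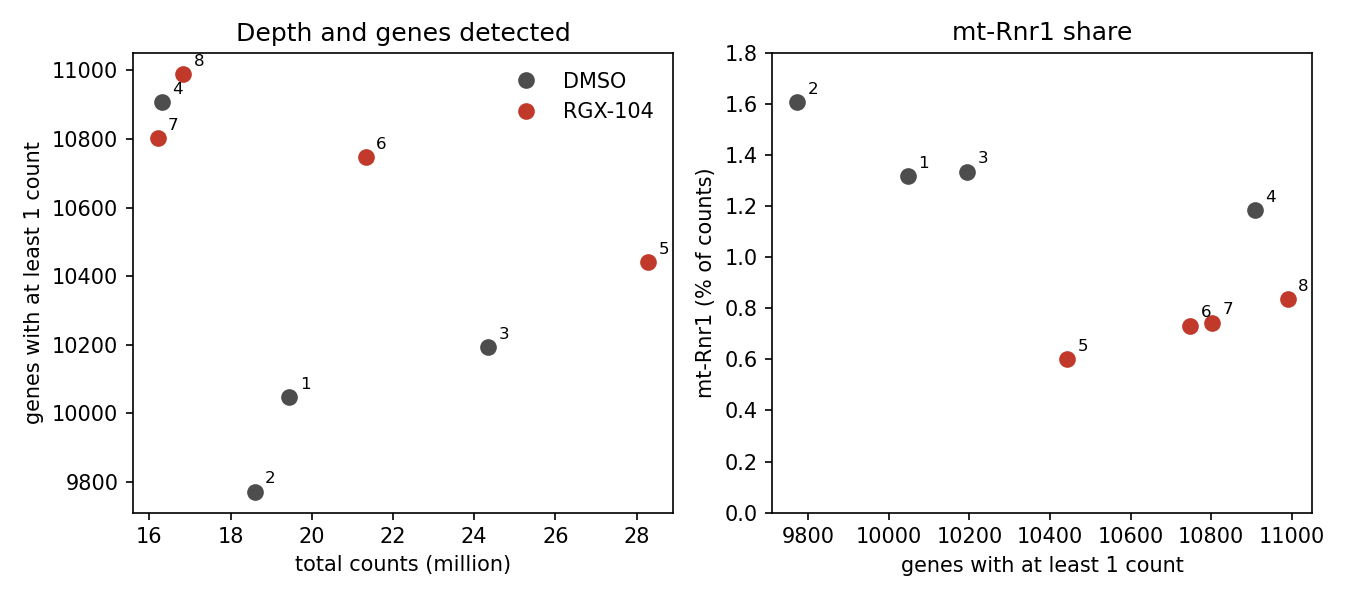
Genes with at least 1 count against total counts (left), and the share of counts from mt-Rnr1 in percent against genes with at least 1 count (right), 1 point per library, numbered by replicate, DMSO in grey and RGX-104 in red. DMSO replicates 1 to 3 lie at 9772 to 10194 genes, and the mt-Rnr1 share is 1.18% to 1.61% in DMSO and 0.601% to 0.835% in RGX-104.

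Of 10037 genes tested, 10 were higher and 1 was lower in RGX-104 (edgeR quasi-likelihood test, adjusted p under 0.05). The rest did not pass, which does not show that they were unchanged. In simulated data the test recovered 29.6% of 2-fold changes at 50 CPM or more and 2.37% below 50 CPM. The strongest increases were those of Abca1, a cholesterol exporter of the plasma membrane, from 6.61 ± 5.59 to 346 ± 34.8 CPM, and of Scd2, a stearoyl-CoA desaturase that makes monounsaturated fatty acids, from 15.4 ± 7.32 to 585 ± 34.0 CPM (mean ± SD, n = 4 per group). The gene that fell was mt-Rnr1, the small ribosomal RNA of the mitochondrion. At an unadjusted p under 0.05 there were 382 genes, 199 higher and 183 lower. DESeq2 called 27 higher and 19 lower genes, among them all 11 called by edgeR.

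The LXR targets were higher as a list. Of 25 listed genes 11 could be tested, and 7 of these were higher, or 8 adjusted over the list alone, with none lower. Their median log2 fold change was 1.66 (camera, adjusted p = 2.08e-34, and adjusted p = 0.00139 with an estimated correlation). Abca1 rose by a log2 fold change of 5.68 ± 0.65 (SE, adjusted p = 8.64e-05), with 1 DMSO library at 0 counts. Scd2 rose by 5.23 ± 0.27 (adjusted p = 7.29e-10) and Abcg1, a second sterol exporter, by 3.36 ± 0.29 (adjusted p = 2.56e-06), from 74.4 ± 42.1 to 773 ± 56.1 CPM. Srebf1, which encodes the transcription factor that governs fatty acid synthesis, rose by 2.39 ± 0.16 (adjusted p = 3.45e-08), from 90.8 ± 7.61 to 480 ± 80.9 CPM. Mylip, a ubiquitin ligase, rose by 1.66 ± 0.18 (adjusted p = 3.41e-05), from 79.2 ± 12.9 to 254 ± 21.4 CPM. Arl4c, a small GTPase, rose by 0.68 ± 0.10 (adjusted p = 0.00375), from 664 ± 60.1 to 1076 ± 57.4 CPM. In each of these genes all 4 RGX-104 libraries lay above all 4 DMSO libraries.

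The list members that did not pass over all genes were Lpcat3, at 75.4 ± 16.9 CPM in DMSO and 110 ± 6.77 CPM in RGX-104, Apoe (16.5 ± 14.6 and 24.4 ± 9.13 CPM), Smpdl3a (35.2 ± 17.6 and 35.1 ± 14.1 CPM) and Scd1 (1.52 ± 2.73 and 7.13 ± 5.51 CPM). The 14 other members were too low to test, and 7 of the listed genes had no count in any library. Of the receptors, Nr1h2 (LXRβ) was measured at 49.4 ± 14.9 CPM in DMSO and 43.3 ± 12.4 CPM in RGX-104 (log2 fold change -0.21, adjusted p = 1.00). Nr1h3 (LXRα), itself a listed target, had 4.78, 0, 0 and 6.93 CPM in the DMSO libraries and 1.03, 0, 0 and 0 CPM in the RGX-104 libraries, and was not tested.

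On GRCm38.p6 these genes lie at chromosome 4, 53030789 to 53159988 (Abca1), chromosome 19, 44293676 to 44306864 (Scd2), chromosome 17, 31057694 to 31117984 (Abcg1), chromosome 11, 60199084 to 60224186 (Srebf1), chromosome 13, 45389742 to 45411940 (Mylip) and chromosome 1, 88698225 to 88702191 (Arl4c). All are annotated as protein-coding. Srebf1 overlaps Rai1, which was at 147 ± 14.9 CPM in DMSO and 176 ± 25.7 CPM in RGX-104 and was not called (log2 fold change 0.25, adjusted p = 1.00). Scd2 belongs to a family of close paralogs on the same chromosome, and reads shared with Scd1 or Scd4 may have been split between them, so its value is uncertain to that extent. Abca1 lost its call with a robust dispersion (adjusted p = 0.757) and moved to 7.32 with limma-voom and to 6.31 without DMSO replicate 3. Against DMSO replicate 4 alone, Abcg1 was at 4.69 and Scd2 at 6.05 on the log2 scale, and with the number of genes detected as a covariate Abcg1 was at 4.05.

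**Figure D2:**
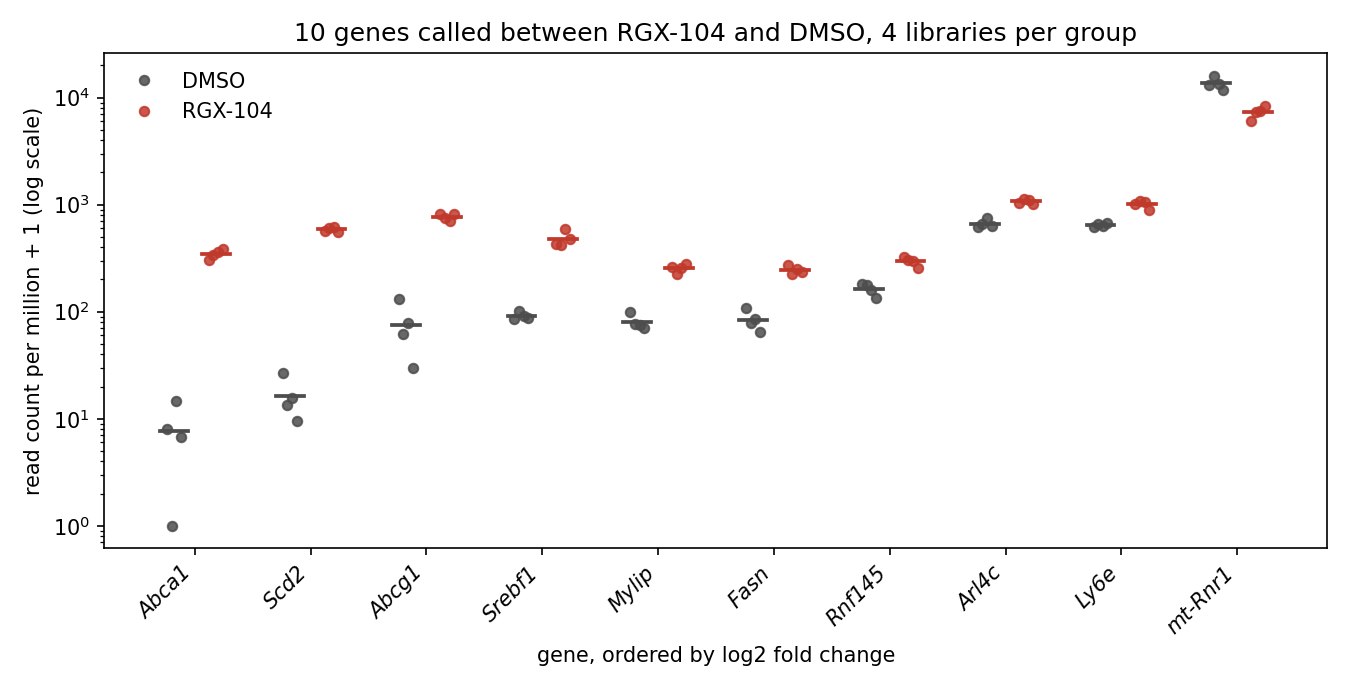
CPM plus 1, on a log scale, of 10 of the 11 genes called between RGX-104 (red) and DMSO (grey), 1 point per library, with a bar at the mean of 4 libraries. All RGX-104 libraries lie above all DMSO libraries for 9 genes and below them for mt-Rnr1, where the means are 7281 and 13613 CPM.

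Genes of fatty acid synthesis and desaturation were higher as a list. Of 18 tested members 2 rose, Scd2 and Fasn, and 4 did so adjusted over the list alone, which adds Acaca and Acsl3. The median log2 fold change was 0.38 (camera, adjusted p = 5.29e-07, and adjusted p = 0.0119 with an estimated correlation), and it was 0.75 against DMSO replicate 4 alone and 0.57 with the genes detected as a covariate. Fasn, the fatty acid synthase and also a member of the LXR list, rose by 1.54 ± 0.19 (edgeR, adjusted p = 1.75e-04), from 82.9 ± 17.9 to 244 ± 20.6 CPM. Acaca, which encodes acetyl-CoA carboxylase, was at 13.3 ± 8.76 CPM in DMSO and 43.7 ± 6.59 CPM in RGX-104, and Acsl3, a ligase that activates long-chain fatty acids, at 15.7 ± 8.58 and 47.1 ± 17.1 CPM. Elovl5, Tecr and Acss2 had log2 fold changes of 0.28, -0.08 and -0.26 and did not pass. Without the members shared with the LXR list, 15 genes remained with a median of 0.28 (camera p = 0.00272, and p = 0.0219 with an estimated correlation), a comparison added after seeing the data. Fasn lies at chromosome 11, 120805958 to 120825166.

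Genes of cholesterol synthesis and uptake were higher as a list by camera, although 1 of 23 tested members passed by itself. The median log2 fold change was 0.73, with 20 members above 0 and 3 below (adjusted p = 9.84e-05). The call was lost with an estimated correlation (adjusted p = 0.102) and against DMSO replicate 4 alone (median 0.53, adjusted p = 0.128), where a group of 1 library leaves less precision. It was kept narrowly with the genes detected as a covariate (median 0.50, adjusted p = 0.0492). Of the members that did not pass, Hmgcs1 was at 24.7 ± 10.8 CPM in DMSO and 29.9 ± 4.76 CPM in RGX-104, and Srebf2, a transcription factor of sterol synthesis, at 162 ± 31.8 and 216 ± 33.3 CPM. Only 4 tested members had a mean of 50 CPM or more. DMSO replicates 1 to 3 also had the fewest genes detected, 9772 to 10194 against 10442 to 10990 in the RGX-104 libraries.

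Among the called genes outside these lists, Ly6e, a GPI-anchored surface protein of lymphocytes, rose by 0.64 ± 0.11 (edgeR, adjusted p = 0.00987), from 641 ± 23.4 to 1009 ± 88.0 CPM (chromosome 15, 74955025 to 74959904). Rnf145, a ubiquitin ligase of the endoplasmic reticulum, rose by 0.84 ± 0.16 (adjusted p = 0.0352), from 162 ± 21.9 to 294 ± 27.8 CPM (chromosome 11, 44518793 to 44565520). It overlaps Gm51891, a long noncoding RNA at a mean of 7.04 CPM. Rnf145 lost its call when any 1 of DMSO replicates 2, 3 and 4 or RGX-104 replicates 5, 6, 7 and 8 was left out (adjusted p from 0.0689 to 0.256). Ly6e lost it without DMSO replicate 3 (adjusted p = 0.0586), RGX-104 replicate 6 (0.109) or RGX-104 replicate 7 (0.0962), and Ly6e, Arl4c and Rnf145 lost it with the genes detected as a covariate (adjusted p = 0.308, 0.115 and 0.0538), at log2 fold changes of 0.62, 0.70 and 1.05. These genes also lost their calls in the test against a fold of 1.2, and Rnf145 did with 1 surrogate variable. Against DMSO replicate 4 alone the log2 fold changes of Ly6e, Arl4c and Rnf145 were 0.56, 0.74 and 1.10.

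The single lower gene, mt-Rnr1, fell by 0.92 ± 0.09 on the log2 scale (edgeR, adjusted p = 1.10e-05), from 13613 ± 1781 to 7281 ± 960 CPM. It lies on the mitochondrial chromosome at 70 to 1024 and is annotated as a ribosomal RNA. Its share of the counts was 1.36% ± 0.18 in DMSO and 0.728% ± 0.096 in RGX-104. The large ribosomal RNA of the mitochondrion, mt-Rnr2, named here after its values were seen, took 4.74% ± 0.75 and 3.88% ± 0.55 of the counts and was not called (log2 fold change -0.31, adjusted p = 1.00). It was called by limma-voom (adjusted p = 0.0275) and without a filter (adjusted p = 4.16e-04). The fit without a filter gave far smaller p-values for strong genes (edgeR p of Scd2 1.73e-157, against 7.27e-14 with it), so its calls carry less weight.

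Genes of naive and quiescent T cells were slightly lower as a list by camera, with no member passing over all genes. Of 21 tested members 15 had a log2 fold change below 0 and 6 above, with a median of -0.12 (adjusted p = 0.00105). The call was lost with an estimated correlation (adjusted p = 0.252), with fry (adjusted p = 0.138) and with the genes detected as a covariate (adjusted p = 0.103), and against DMSO replicate 4 alone the median was 0.00244. Adjusted over the list alone 1 gene was lower, Lef1, a transcription factor of naive T cells, named after its values were seen, at 355 ± 15.7 CPM in DMSO and 239 ± 27.7 CPM in RGX-104 (log2 fold change -0.59 ± 0.14, edgeR adjusted p = 0.348, DESeq2 adjusted p = 2.08e-04). At an unadjusted p under 0.05 edgeR had 4 members lower, DESeq2 called 1 and limma-voom 0. Among the 6 members above 0 were Tcf7, Klf2 and Ccr7, with log2 fold changes of 0.06, 0.07 and 0.13, which did not pass. Genes detected were fewest in DMSO replicates 1 to 3, at 9772 to 10194.

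No effector gene passed. Of 39 listed genes 20 were tested, 10 with a log2 fold change above 0 and 10 below, with a median of 0.002 (camera, adjusted p = 0.969). Of these, 7 had a mean of 50 CPM or more. The mean was -0.05 and camera's direction was down, while fry's was up, and the median moved to -0.01 with DESeq2 size factors, as the median of all tested genes moved from 0.01 to -0.01. None had an unadjusted edgeR p under 0.05, and DESeq2 and limma-voom called 0. Gzmb, the cytotoxic protease granzyme B, was at 9.72 ± 7.38 CPM in DMSO and 14.4 ± 1.93 CPM in RGX-104, and Eomes at 8.93 ± 2.56 and 7.41 ± 3.47 CPM. Ifng and Tbx21 (interferon gamma and the transcription factor T-bet) had no count in any library. For 3 counts over a group this allows up to 0.0381 CPM in DMSO and 0.0363 CPM in RGX-104, for counting error of independent reads only. By the estimate above, 1 apparent molecule in a library corresponds to 2.90 to 5.48 CPM. Transcripts well above these limits could therefore have been missed. In simulated data 2.37% of 2-fold and 41.3% of 8-fold changes below 50 CPM were recovered, so moderate changes of low effector genes were not detectable here.

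T cell activation genes were not called as a list by camera (36 tested members, median log2 fold change 0.18, adjusted p = 0.217), whereas fry gave an adjusted p of 0.04995. No member passed over all genes or adjusted over the list alone, with 5 members at an unadjusted edgeR p under 0.05, 3 higher and 2 lower, and 0 calls by DESeq2 and limma-voom. Cd44 was at 7.58 ± 6.15 CPM in DMSO and 10.4 ± 8.16 CPM in RGX-104, and Il2ra, the high-affinity chain of the interleukin 2 receptor, at 5.33 ± 7.13 and 5.94 ± 7.68 CPM. The inhibitor of NF-κB Nfkbia was at 491 ± 120 and 726 ± 102 CPM (log2 fold change 0.54, adjusted p = 0.908), and it was called with counts divided by the apparent reads per molecule (0.54, adjusted p = 0.00788). That setting gave far smaller p-values for strong genes than the main fit, so its calls carry less weight.

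**Figure D3:**
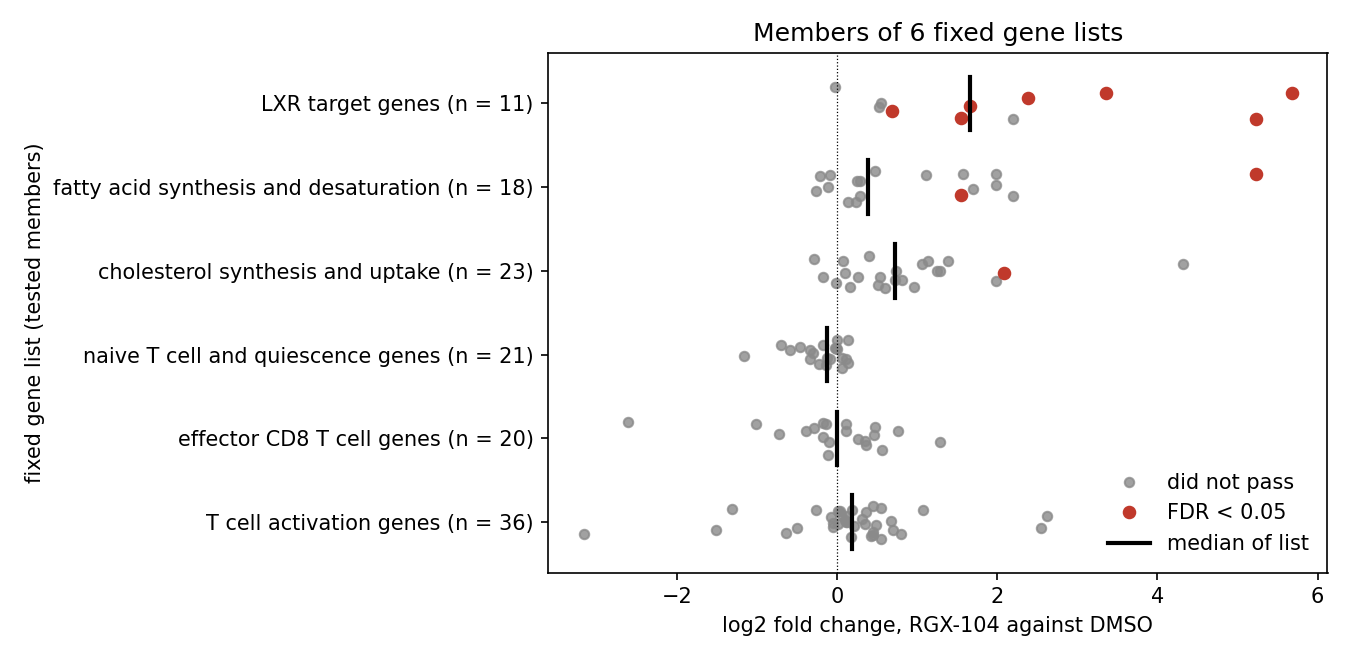
Log2 fold change of RGX-104 against DMSO for the tested members of 6 fixed lists, 1 point per gene, red where the edgeR adjusted p is under 0.05, with a black bar at the list median; vertical scatter within a list carries no value. The medians are 1.66 for LXR targets, 0.38 for fatty acid synthesis, 0.73 for cholesterol synthesis, -0.12 for naive, 0.002 for effector and 0.18 for activation genes.

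Of the genes of CD8 T cell identity, Cd8a was at 668 ± 33.8 CPM in DMSO and 739 ± 23.1 CPM in RGX-104, without overlap between the groups but not called (log2 fold change 0.13, edgeR adjusted p = 1.00), and Cd8b1 at 719 ± 30.0 and 716 ± 60.3 CPM. The summed level of 14 CD8 T cell identity genes was 5227 ± 105 and 5544 ± 223 CPM (exact permutation p = 0.0857). Markers of other cells were low: B cell markers summed to 145 ± 73.8 and 164 ± 38.2 CPM, macrophage markers to 185 ± 48.6 and 171 ± 20.003 CPM, and markers of CD4 and regulatory T cells to 111 ± 11.8 and 101 ± 18.7 CPM. Dendritic cell markers summed to 974.7 ± 164 and 1024 ± 110 CPM, a list that holds Ccr7 and Bst2, which T cells also express. Natural killer, neutrophil, erythroid and stromal markers summed to 9.97 ± 9.33, 9.17 ± 18.3, 29.2 ± 21.6 and 88.6 ± 29.5 CPM in DMSO and to 8.50 ± 3.00, 8.91 ± 6.59, 19.3 ± 6.79 and 96.6 ± 22.8 CPM in RGX-104. Ribosomal protein genes took 17.1% ± 1.00 and 17.5% ± 0.83 of the counts. None of these 10 lists had an unadjusted exact p under 0.05, but adjusted over 10 lists a single list could not have passed, so a difference in identity or composition is not excluded by this test.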

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

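The tests of the mt-Rnr1 to mt-Rnr2 ratio, of exchanged libraries and of balanced splits were chosen after the results were seen, and the covariate was added once uneven detection had been seen. In 81 groups of 4 libraries examined, 5 had a library far from the other 3, where chance gives about 4; 4 of them are given here.

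Nr1h3 stood at 1.03 CPM in RGX-104 replicate 5 and at 0 in the other 3. Scd1 stood at 5.60 CPM in DMSO replicate 1, against 0 to 0.493 CPM in the other DMSO libraries. The summed CD8 T cell identity genes stood at 5384 CPM in DMSO replicate 4, against 5159 to 5192 CPM, and the summed neutrophil markers at 36.7 CPM in the same library and at 0 in the other DMSO libraries.

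The fall of mt-Rnr1 was weighed against uneven detection and against a general loss of mitochondrial ribosomal RNA. With the number of genes detected as a covariate the log2 fold change was -0.85 (95% interval -1.10 to -0.60, edgeR adjusted p = 0.00311), so uneven detection as the whole cause is argued against. The log2 ratio of mt-Rnr1 to mt-Rnr2 was -1.80 ± 0.34 in DMSO and -2.41 ± 0.03 in RGX-104 (exact permutation p = 0.0286, the smallest that 4 against 4 can give), which argues against an equal loss of both RNAs. The ratio was chosen once mt-Rnr1 was known to be called and mt-Rnr2 not, so its p is not independent of the call. The summed 22 mitochondrial tRNA genes stood at 994 ± 166 and 1009 ± 157 CPM. An effect of the agonist may account for the fall, and so may a difference between the groups in RNA extraction or in priming on this RNA, which was not tested.

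The lower naive T cell list was weighed against uneven detection and against Lef1 alone. With the covariate the camera p was 0.0224 and the median -0.11, and without Lef1 the p was 0.00185 and the median -0.11. Both values met the bound set beforehand for setting these explanations aside, but of the 18 balanced splits, with 2 libraries of each group on both sides and so no treatment contrast, 2 and 1 gave a p as small in the same form of the test, and 6 and 5 a p under 0.05. The real split gave a p of 1.83e-04, and 2 of the 35 splits, the real split included, were as small, the other at 7.11e-06, so chance is not excluded. Uneven detection, Lef1 alone and an effect of the agonist cannot be told apart for this list, because the set test is not calibrated for its members in these libraries.

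The higher cholesterol list was weighed against uneven detection and inflated folds of genes near dropout. Its camera p was 0.00641 with the covariate (median 0.50) and 1.13e-04 over the 13 members at 20 CPM or more (median 0.51), and the lowest p of the 18 balanced splits in the same form was 0.0258 and 0.0782. With the covariate the list thus met the bound set beforehand against uneven detection, at the preset correlation only. The balanced splits never hold DMSO replicates 1 to 3 on the same side, so they cannot show what uneven detection alone gives. Uneven detection as the whole cause is therefore not excluded. With the covariate the camera p was 0.0492 after adjustment over the lists. Without it the call was lost with an estimated correlation (adjusted p = 0.102). Inflated folds are not excluded, because 20 CPM amounts to few apparent molecules, 1 of which corresponds to 2.90 to 5.48 CPM. In the 4 splits that exchange 1 library and keep DMSO replicates 1 to 3 together the p was 8.19e-05 to 0.00109, and in the 12 others that exchange 1 library, with as much of the treatment contrast left, it was 0.0288 to 0.141. The list may therefore follow detection in part or as a whole. An effect of the agonist or inflated folds of members near dropout may also account for it.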

How the results depend on the processing

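All 11 calls were kept with DESeq2, limma-voom, no filter, the filter of at least 10 counts in 4 libraries and the 3 other normalizations. Scd2, Abcg1, Srebf1, Mylip and Fasn were kept in all 22 alternatives, and mt-Rnr1 in the 21 that held it. Abca1 was kept in 21, Arl4c in 19, Ly6e in 16 and Rnf145 in 11. The surrogate variable set DMSO replicate 2 apart (-0.928, against 0.0805 to 0.223 in the other libraries). That alternative therefore largely repeats the removal of this library. The alternatives with DMSO replicate 4 alone, with the genes detected as a covariate and with counts per apparent molecule were chosen after seeing the data. No paired analysis was possible because the labels name no pairs. Library numbers run on across the groups, so a pairing that the labels leave out is not excluded, and the test would ignore it.

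The count of higher genes was 27 with DESeq2 and 6 with the covariate, against 10. The count of lower genes was 19 with DESeq2, 4 without a filter, 3 with limma-voom, 2 with counts per apparent molecule and 0 without mitochondrial and ribosomal protein genes, which removes mt-Rnr1 by construction. The lower genes were mt-Rnr1, mt-Rnr2 and Ankhd1 with limma-voom, these and Malat1 without a filter, and mt-Rnr1 and Ankhd1 per apparent molecule. Without a filter and per apparent molecule the edgeR p of Scd2 was 1.73e-157 and 1.19e-100, against 7.27e-14 in the main fit. Values this small from 8 libraries point to an understated spread, so calls made only in these settings carry less weight. The share of higher calls was 90.9% by edgeR, 58.7% by DESeq2, 78.6% by limma-voom and 73.3% without a filter. Leaving out 1 library gave 7 to 11 higher and 1 to 3 lower genes, the 3 without DMSO replicate 4. DMSO replicate 4 alone gave 7 higher and 1 lower, 7 of them among the 11. The added DESeq2 calls include genes with no count in 1 of the groups, such as Spats2, Scd4 and Zfp119a, named after their values were seen. Their DESeq2 log2 fold changes were 9.63, 9.66 and -10.3. Other added calls, such as Lef1 and Ankhd1, had counts in both groups. The cause of the larger DESeq2 count was not tested.

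The LXR list kept its call in each alternative run, with a median of 1.56 to 1.78 when 1 library was left out. The naive list kept a median of -0.12 but not its call with an estimated correlation (adjusted p = 0.252) or fry (0.138), and had -0.11 with the covariate and 0.00244 against DMSO replicate 4 alone. Leaving out 1 library gave -0.13 to -0.08. The effector median turned from 0.002 to -0.0137 with DESeq2 size factors, a shift shared by all genes, whose median went from 0.00904 to -0.00726. It lay between -0.127 and 0.0821 when 1 library was left out, uncalled each time. The activation median of 0.18 passed with fry alone, and leaving out 1 library gave 0.132 to 0.313, the highest without DMSO replicate 2 (adjusted p = 0.0596). The causes of the other changes were not tested. Low genes were measured least precisely: the median biological coefficient of variation was 0.790 under 50 CPM and 0.255 for the 3544 genes at 50 CPM or more.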

Other observations

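The tests of genes silent in a group and the genes named in this part were chosen after the data were seen, apart from the fixed lists and the splits.

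None of the other lists was called by camera against all other genes, while fry called 3. By camera, cell cycle genes (29 tested, median log2 fold change 0.15, adjusted p = 0.485), interferon response genes (31, 0.12, 0.717), inhibitory receptor genes (6, 0.03, 0.577), nuclear oxidative phosphorylation genes (44, 0.07, 0.301) and fatty acid oxidation and lipid droplet genes (23, 0.09, 0.717) were not called. Neither were stress response genes of the endoplasmic reticulum (25, 0.26, 0.301), apoptosis and survival genes (23, 0.23, 0.104), heat shock genes (17, -0.02, 0.717), glycolysis genes (19, -0.004, 0.368), cytokine and chemokine receptor genes (25, 0.004, 0.344) and ribosomal protein genes (59, 0.02, 0.0768). For the receptor genes camera's direction was down although the median was above 0. Fry called the cell cycle list and the receptor list, up and down (adjusted p = 0.0395 for each), and the apoptosis list upward (0.0185). CD8 identity (13, 0.07, 0.640), B cell (10, -0.08, 0.996), CD4 T cell (5, 0.07, 0.972), macrophage (6, -0.03, 0.763), dendritic cell (6, -0.12, 0.717) and erythroid lists (3, -1.28, 0.927) were not called, and for B cell markers the mean was 0.06. Natural killer, neutrophil and stromal markers had too few tested members, and mitochondrially encoded protein genes none. Adjusted over the list alone, Slc2a3, a glucose transporter, was lower, at 109 ± 27.8 CPM in DMSO and 56.5 ± 13.8 CPM in RGX-104 (edgeR adjusted p over all genes 0.872).

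Scd4, a further stearoyl-CoA desaturase, had no count in any DMSO library and 4.41 to 12.1 CPM in the RGX-104 libraries (edgeR adjusted p = 0.872, DESeq2 adjusted p = 2.88e-04). These values amount to few apparent molecules, 1 of which corresponds to 2.90 to 5.48 CPM, and reads shared with Scd2 are not excluded. Ankhd1 was at 193 ± 41.9 CPM in DMSO and 97.9 ± 14.7 CPM in RGX-104 (edgeR adjusted p = 0.0792, DESeq2 adjusted p = 1.33e-04). Malat1, a nuclear noncoding RNA, was at 13999 ± 3395 and 11314 ± 1148 CPM and was not called by edgeR (log2 fold change -0.32), except without a filter (adjusted p = 0.0142) and without DMSO replicate 4 (log2 fold change -0.47, adjusted p = 0.0218), and against DMSO replicate 4 alone its log2 fold change was 0.20.

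Scd4 was 1 of 21 genes with reads in every RGX-104 library and in no DMSO library, and 3 genes had the opposite pattern. A candidate explanation is the lower detection in DMSO replicates 1 to 3. Of the 4 other splits that keep these libraries together, the highest gave 20 such genes, and so did 1 split that does not keep them together. The bound set beforehand asked only for more than each of these splits, and 21 against 20 is within counting spread, so that bound was set aside and lower detection stays in place as an explanation.

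The 35 splits of the 8 libraries into 4 and 4 were each tested as the real split was. For genes higher in RGX-104 the real split gave 10 and the highest other 0, and for lower genes 1 and 0 (edgeR). In each direction 1 of 35 splits was as large, the smallest share that 35 splits can give. Chance is thus unlikely but not excluded for the higher genes. For the lower direction a single called gene decides the test, so it carries little weight. The other splits had 226 to 345 genes at an unadjusted p under 0.05 against 382 in the real split, and they were not run with another tool. The camera p of the LXR list was 9.03e-36 against 4.56e-12 in the next split, that of the fatty acid list 4.60e-08 against 8.52e-05, and that of the cholesterol list 1.28e-05 against 8.19e-05, each with 1 of 35 splits as small. Other splits called up to 6 lists, where the real split called 4. Those with 5 or 6 exchange 1 library of each group and so keep part of the treatment contrast. Their counts alone do not separate a structure of the libraries from treatment. The balanced splits, which hold no treatment contrast, called up to 3 lists, so some lists were called without it. All splits with 5 or 6 lists keep DMSO replicates 1 to 3 together, and the remaining exchange split that does so called 2. The splits that exchange 1 library and part these replicates called 1 to 4 lists, with as much of the treatment contrast left.

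Genes whose groups did not overlap numbered 357 (3.56% of those tested), where chance gives 2.86%.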
